A study of Danio rerio with 12 samples.

How the data were processed

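DNA methylation was measured in pools of zebrafish embryos (Danio rerio) at 72 hours post fertilisation by digital restriction enzyme analysis of methylation (DREAM), a sequencing assay that reads the methylation state of CCCGGG sites. Per the labels' protocols, SmaI cut the unmethylated sites first and XmaI then cut the remaining ones, so that a fragment end beginning with GGG came from an unmethylated site and an end beginning with CCGGG from a methylated site. Per the labels, 2.5 micrograms of DNA were used, 8 spiked standards of known methylation were added before digestion, and libraries were amplified with 12 PCR cycles. The labels name pools of 20 embryos. Exposed pools received sodium arsenite, a soluble form of inorganic arsenic, at 0.1 mM or 1 mM for 72 hours, and control pools received none. The aligner and its settings are not given in the sources used here. The genome build is danRer7, per the submitters' processing notes.

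The deposited files held, for each library, 64466 CCCGGG sites on 25 chromosomes with methylated and unmethylated reads, a raw level and an adjusted level. The columns of methylated and unmethylated reads were taken to be in the unit of expected counts, because the authors placed a correction factor, which is not a whole number, in the same deposited column; all site values were whole and no rounding was needed. The levels deposited by the authors are in percent. The raw level equalled the methylated share of reads with 0.5 added to each kind of read, to within 0.005 points. The adjusted level equalled the same share after multiplying the methylated reads by the library's correction factor, to within 0.015 points. That factor was between 1.198 and 1.324 and, per the series' design text, came from the spiked standards. The factor raises levels, while the 0.5 added to each kind of read raises those near 0% and lowers those near 100%. The levels given here are the unadjusted shares of reads, and they lay below the adjusted ones in 6498 of 6528 values of single libraries at sites of 10 to 90%, in 2808 of 2808 at sites under 10% and in 12835 of 18096 at sites over 90%. A table of the whole series held the adjusted levels of 1533 sites; they were equal to those in the library files, and all 1533 sites with at least 100 reads in each library were the ones listed. All 12 value columns of that table were matched to a sample by title, and 0 were left without a sample.

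Sites with at least 20 reads in each of the 12 libraries were analysed, 2286 in all. The 2228 of them with at least 1 methylated and 1 unmethylated read over the 12 libraries were tested one by one with edgeR 4.0.16 in R 4.3.3. The model had a coverage term for each library and a group term on the methylated reads, was fitted to all 12 libraries, and used the quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. The design, the coverage minimum, the alternatives and the rule for naming sites were fixed before the data were examined, and alternatives added later are named as such. By that rule, called sites whose groups do not overlap would be named, up to 12 rising and 12 falling; where fewer than 6 sites passed in a comparison, the 6 with the smallest p are named and stated not to pass. Mean methylation per library, over all sites and in 3 classes set by the mean of all 12 libraries (under 10%, 10 to 90%, over 90%), was compared with exact two-sided permutation tests over 70 splits of 4 against 4 libraries, for which 0.0286 is the smallest p possible. Intervals of these differences are 95% intervals obtained by inverting the same test. Intervals of single sites came from limma 3.58.1 on log2 odds with a pseudocount of 1. Summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

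The test was checked on simulated data for the comparison of 1 mM with control. In 20 simulated data sets of 2199 sites, with 200 sites changed and the replicate spread of the real libraries, edgeR recovered 0.746% of sites whose odds of methylation changed by a factor of 1.5, 11.9% at a factor of 2 and 48.6% at a factor of 4. Among sites at 10 to 90% methylation the recovered shares were 2.16%, 33.5% and 90.2%. Of all calls, 2.64% were false. In the real libraries the median replicate SD was close to the median binomial SD at sites under 10% (0.0696 and 0.0736 points) and over 90% (0.791 and 0.765). The simulated spread at these sites may be wider than the real one, so the shares recovered over all levels may be too low.

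Libraries held between 1425613 and 1822127 reads at listed sites, and the median depth of an analysed site was between 309.0 and 431.5 reads per library. Reads carried no molecular identifiers, so binomial intervals and the limits set by a count of 0 (3 counts) cover counting error only. Every pair of replicates differed in depth by more than counting error, with a chi-square of at least 7.42 per degree of freedom in the 18 pairs within groups, so no library was counted as a duplicate. The labels do not say whether pools came from separate spawnings, and p-values therefore measure the spread between these pools.

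Alternatives were coverage minimums of 10, 50 and 100 reads, sites at 5 to 95% only, limma, a quasi-binomial model, the 2 compared groups alone, the replicate number as a block, centred libraries, adjusted levels, a change of at least 10 points, and leaving out each library. No annotation of danRer7 was used here, so sites are named by chromosome and position, and the 16 gene lists and the comparison by genomic context fixed beforehand were not analysed here.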

Results

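Methylation at CCCGGG sites was compared between 4 control pools, 4 pools exposed to 0.1 mM sodium arsenite and 4 pools exposed to 1 mM, to ask whether arsenite alters DNA methylation in zebrafish embryos. Control libraries held 1425613 to 1666841 reads, those of the 0.1 mM group 1485862 to 1822127, and those of the 1 mM group 1491247 to 1700854. Reads were concentrated in few places: the 2286 analysed sites, 3.55% of those listed, took 88.3 to 95.1% of the reads of a library. Of these sites, 80.9% had their nearest listed CCCGGG at 100 to 600 bp, against 17.2% of listed sites, as sequencing needs a short fragment between neighbouring cuts.

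The embryo genome was heavily methylated at these sites. The median site was methylated at 95.6%, and 1508 sites (66.0%) lay over 90%. A smaller set of 234 sites (10.2%) lay under 10%, 212 of them under 1%, and 544 sites (23.8%) were in between. Levels were close in all libraries, with Pearson's r across sites between 0.991 and 0.994 for any pair of the 12; sites are not independent replicates. The median SD between replicates was 2.87 points at sites of 10 to 90% and 0.791 points at sites over 90%. The binomial SD that counting error implies had a median of 2.47 and 0.765 points there. The 2 medians are not like for like, as the SD of only 4 libraries tends to lie below the underlying one. Spread beyond counting error is therefore understated by this comparison.

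Overall methylation did not differ detectably with exposure. Averaged over the 2286 sites it was 80.2% ± 0.304 in controls, 80.1% ± 0.251 at 0.1 mM and 80.3% ± 0.191 at 1 mM (SD, n = 4 each). The difference between 1 mM and control was 0.133 points (95% interval -0.49 to 0.57, exact permutation p = 0.457, adjusted over 3 comparisons 0.685). Between 0.1 mM and control it was -0.018 points (-0.73 to 0.51, exact permutation p = 0.857, adjusted 0.857). The 2 doses differed by 0.15 points (-0.37 to 0.66, exact permutation p = 0.343, adjusted 0.685). With 4 against 4 libraries, a single comparison could not pass after adjustment over 3, even at the smallest possible p. The sign of the first difference turned to -0.053 points when the median of sites at 10 to 90% was used. Read-weighted levels gave 0.063 (exact permutation p = 0.914), adjusted levels 0.247 and leaving out single libraries 0.048 to 0.284. Without control library 2 the difference was 0.284 points, with all 4 libraries at 1 mM above the other 3 controls (exact permutation p = 0.0571). That of the second turned to 0.112 with read-weighted levels, to 0.007 with adjusted levels, to 0.067 without 0.1 mM library 2 and to 0.134 without control library 2, while the median of sites at 10 to 90% gave -0.587. That of the third turned to -0.049 with read-weighted levels, and the same median gave 0.534, adjusted levels 0.24 and leaving out single libraries 0.065 to 0.266.

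**Figure D1:**
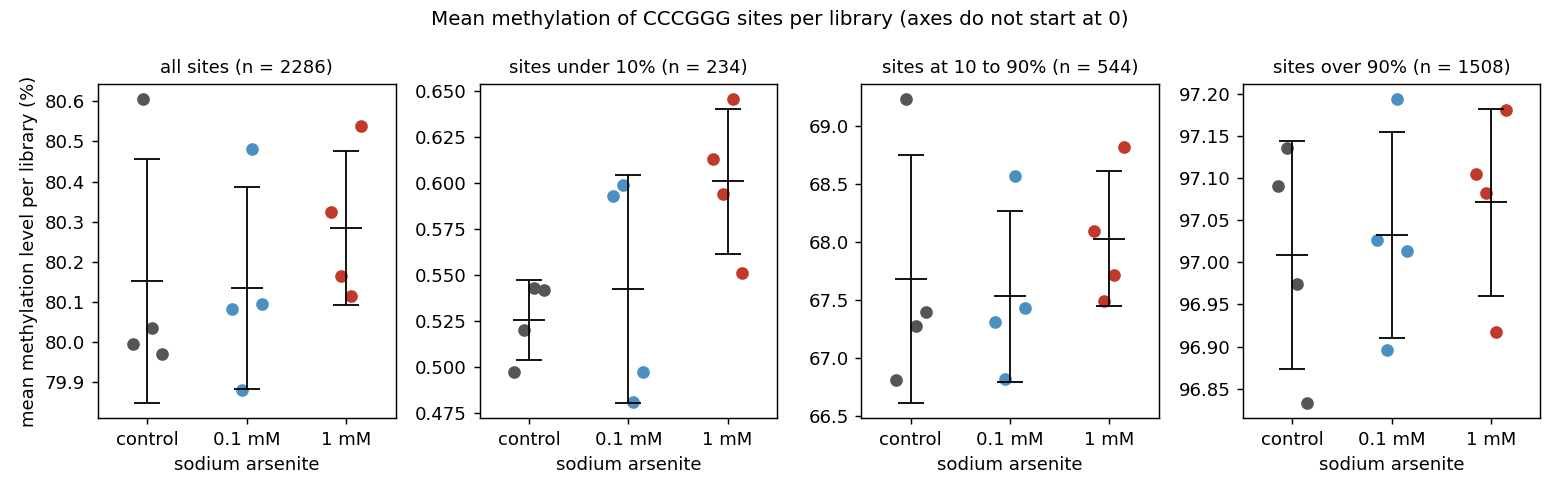
Mean methylation level (%) of each library, over all sites and in 3 classes of sites, against the arsenite concentration. Points are libraries, horizontal bars are group means and error bars are SD (n = 4); over all sites the means lie at 80.2%, 80.1% and 80.3%.

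Sites under 10% gave the smallest p among the classes. They averaged 0.53% ± 0.0218 in controls, 0.54% ± 0.0622 at 0.1 mM and 0.60% ± 0.0397 at 1 mM (SD, n = 4). All 4 libraries at 1 mM lay above the 4 controls, by 0.075 points on average (0.01 to 0.15, exact permutation p = 0.0286), but the adjusted p over the 9 class tests was 0.257. The 2 highest of the 12 libraries in this class, 1 mM libraries 3 and 1 at 0.646% and 0.613%, were those in which the spiked standard with the lowest level was at 1.78% and 2.57%, against 0.215 to 0.920% in controls. The other 1 mM libraries, 2 and 4, had that standard at 0.823% and 0.497% and were at 0.594% and 0.551% in this class, with the highest control at 0.543%. The 0.1 mM libraries 2 and 1 also lay above that control, at 0.599% and 0.593%. Their standard was within the range of the controls, at 0.475% and 0.285%. In a split of this class chosen after seeing the data, its 22 sites at 1 to 10% carried 72.8% of the difference, at 4.21% ± 0.127 in controls and 4.80% ± 0.417 at 1 mM. All 4 libraries at 1 mM, at 4.46 to 5.41%, lay above the controls, at 4.03 to 4.32% (exact permutation p = 0.0286, not adjusted for the choice of the split). Library 1 at 1 mM stood highest, at 5.41% with the other 1 mM libraries at 4.46 to 4.68%. The 0.1 mM libraries 1 and 2, at 4.92% and 4.78%, also lay above the controls. At the 212 sites under 1% the groups overlapped, with 0.126 to 0.158% in control libraries and 0.115 to 0.227% at 1 mM (exact permutation p = 0.457). Intermediate sites averaged 67.7% ± 1.07 in controls, 67.5% ± 0.739 at 0.1 mM and 68.0% ± 0.579 at 1 mM. The interval of the difference between 1 mM and control there was -1.74 to 2.01 points. Sites over 90% averaged 97.0% ± 0.135, 97.0% ± 0.123 and 97.1% ± 0.111. With 4 against 4 libraries, at least 6 of the 9 class tests would need the smallest possible p for any to pass after adjustment, so a difference in a single class could not pass.

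At 1 mM, no single site passed the test against control. The smallest p belonged to a fully methylated site on chromosome 19 at position 16937836 (danRer7), which stood at 99.0% ± 0.128 in controls, with 98.1% to 98.3% in 3 of the 0.1 mM pools and 97.9% in the other, and at 97.2% ± 0.803 at 1 mM (SD, n = 4; at least 422 reads per library; edgeR adjusted p = 0.183). Chromosome 6 position 1501435 was at 99.1% ± 0.236 in controls and had 0 unmethylated reads of 1068 at 1 mM, which allows an unmethylated share of up to 0.281% (edgeR adjusted p = 0.610). The level at chromosome 19 position 38201828 was 98.0% ± 0.447 in controls and 99.1% ± 0.270 at 1 mM. A difference of 5.49 points was seen at chromosome 1 position 1292889, from 85.3% ± 2.63 to 90.8% ± 5.81, where 1 of the 1 mM pools, at 82.2%, lay within the range of the controls. This site was read at a median of 1577.5 reads per library, while the neighbouring site that ends the same reference fragment had a median of 6 reads. Unmethylated sites completed the list, with 0.513% ± 0.425 in controls and 0.109% ± 0.041 at 1 mM on chromosome 6 position 4440116, and 0.090% ± 0.063 and 0.372% ± 0.264 on chromosome 8 position 2751348. The latter difference, 0.282 points, was 0.15 without 1 mM library 3, which was at 0.767% with the other 1 mM pools at 0.209 to 0.264%. The edgeR adjusted p of the 5 sites after the first was between 0.523 and 0.610.

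Among the 2228 tested sites, edgeR called 0 between 1 mM and control, and limma called 0. At an unadjusted p under 0.05 there were 109 sites with edgeR and 103 with limma, where chance alone gives 111.4. The groups did not overlap at 44 sites (1.98%). Chance gives 2.86% where no levels are tied, and less where levels are tied across groups. Mean levels differed by at least 10 points at 11 sites, 7 higher and 4 lower at 1 mM, and the 95% interval lay within 10 points of 0 at 92.2% of all sites and 71.5% of the 544 intermediate ones. Leaving out control library 1 gave 1 called site (chromosome 6 position 4440116, where the difference went from -0.404 to -0.543 points), and leaving out 1 mM library 4 gave 1 (chromosome 1 position 1292889, where it went from 5.49 to 8.37 points). In settings chosen after seeing the data, limma with 50 reads called 2 sites and limma on the deposited table of adjusted levels called the same 2, chromosome 6 position 1501435 and chromosome 19 position 16937836. Without 1 mM libraries 2 and 3, which had 11.6% and 13.1% of their reads at sites over 1000 bp from the next site, against 7.48 to 10.7% in controls, edgeR called 3: the latter site, chromosome 18 position 37192948 and chromosome 8 position 56092585. The calls at the last 2 rested on library 4, at 1.19% and 1.22%, as library 1, the other 1 mM pool kept, was at 0.091% and 0.128% and controls reached 0.154% and 0.082%.

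**Figure D2:**
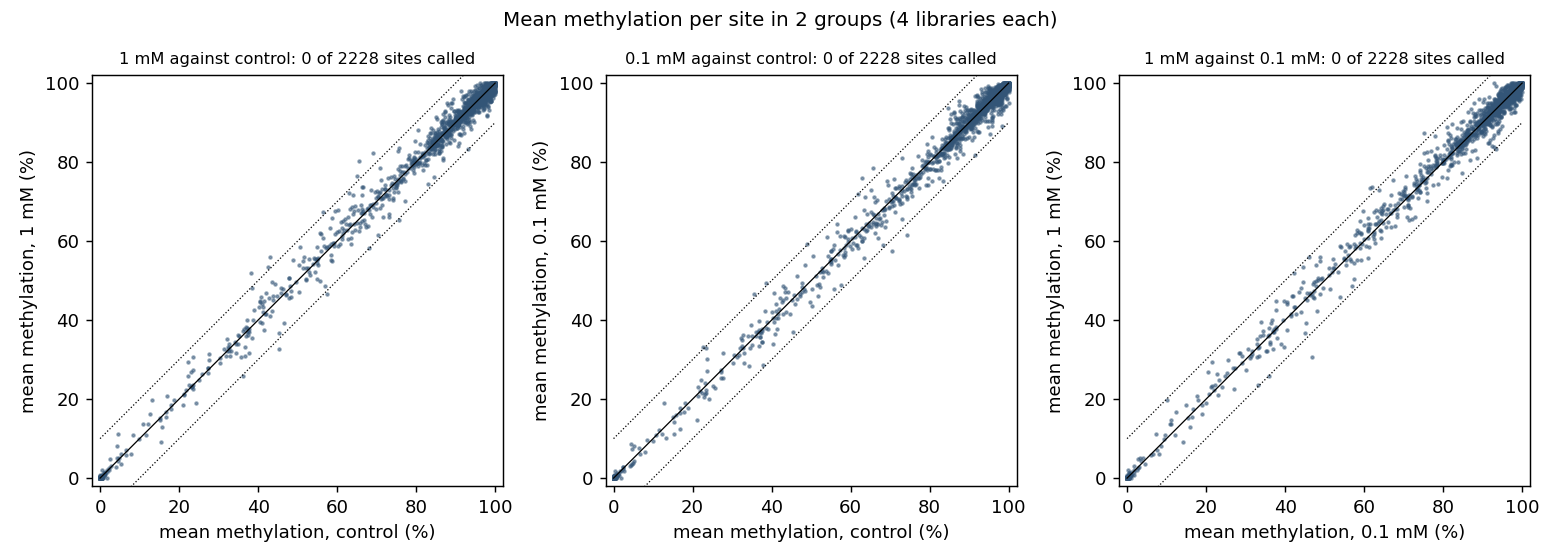
Mean methylation level (%) of each of 2228 sites in one group against another, for 3 comparisons. Each point is a site, the solid line marks equal levels and dotted lines mark differences of 10 points; 11, 9 and 7 sites differ by at least 10 points and 0 sites were called in any panel.

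At 0.1 mM, again no site passed against control. The largest difference among the 6 sites with the smallest p was at chromosome 1 position 1292889, at 85.3% ± 2.63 in controls and 92.3% ± 2.26 at 0.1 mM (SD, n = 4; edgeR adjusted p = 0.0985), where all 4 exposed pools lay above the 4 controls. Chromosome 6 position 4440116 stood at 0.513% ± 0.425 in controls and 0.071% ± 0.036 at 0.1 mM (edgeR adjusted p = 0.0853); its control mean came from 2 pools at 0.866% and 0.893%, with the others at 0.096% and 0.197%. Methylated sites in the list were chromosome 10 position 3853487, at 94.9% ± 1.16 and 97.6% ± 0.408, and chromosome 8 position 43702575, at 87.8% ± 2.74 and 83.6% ± 1.05. The remaining 2 were unmethylated, with 0.064% ± 0.050 and 0.450% ± 0.505 on chromosome 21 position 2066571 and 0.087% ± 0.058 and 0.555% ± 0.837 on chromosome 11 position 21819918. At the former, 2 of the 0.1 mM pools, at 0% and 0.1%, lay within the range of the controls, and without library 1, at 1.09%, the difference went from 0.386 to 0.171 points. The mean at the latter rested on library 2 at 1.81%, without which the difference went from 0.468 to 0.051 points. The edgeR adjusted p of these 4 was between 0.448 and 0.788.

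Of the 2228 sites, edgeR called 0 between 0.1 mM and control, as did limma. Unadjusted p was under 0.05 at 113 sites with edgeR and at 113 with limma, with 111.4 expected by chance. Groups did not overlap at 50 sites (2.24%, with at most 2.86% by chance, less with tied levels). At least 10 points separated the means at 9 sites, 7 higher and 2 lower at 0.1 mM. The 95% interval lay within 10 points of 0 at 92.5% of sites and 73.4% of intermediate ones. The sites on chromosome 1 and chromosome 6 named first were both called with a minimum of 10 reads, with these 2 groups alone and without control library 3; the chromosome 6 site alone was called without control library 1, and the chromosome 1 site alone without 0.1 mM library 4.

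**Figure D3:**
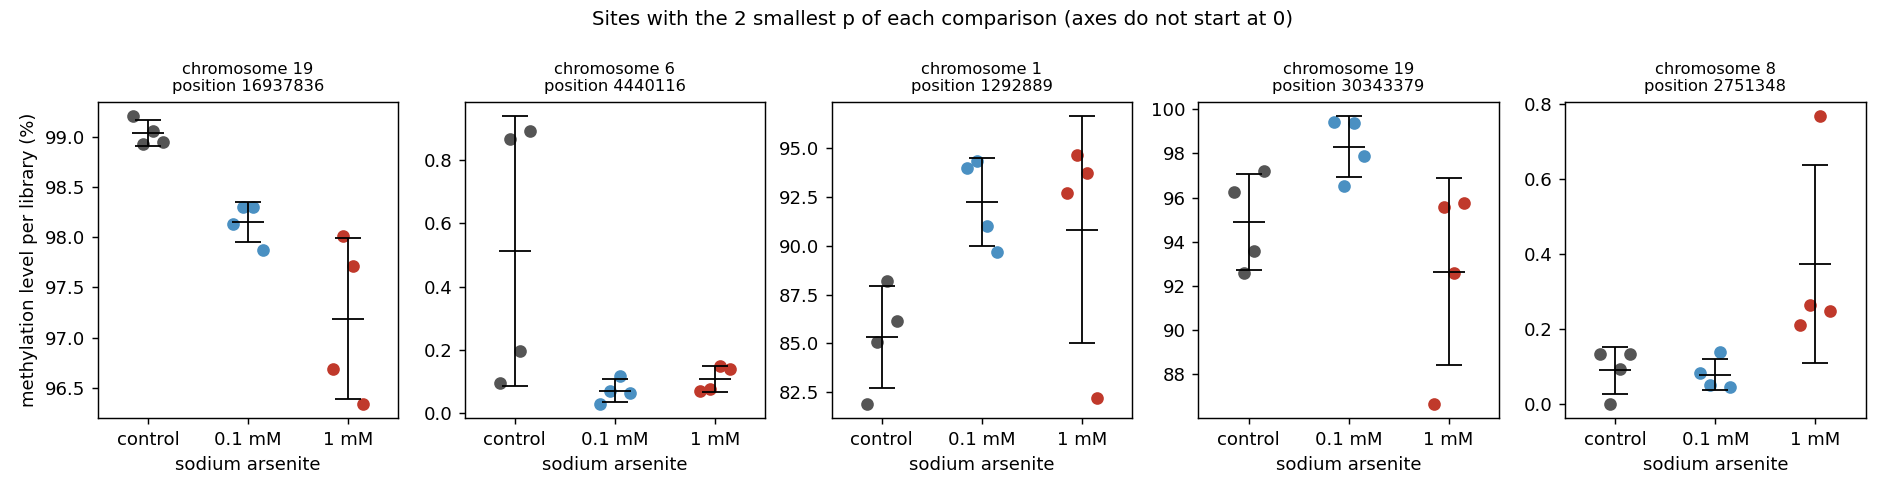
Methylation level (%) of each library at the sites with the 2 smallest p of each comparison, against the arsenite concentration. Points are libraries, horizontal bars are group means and error bars are SD (n = 4); on chromosome 19 position 16937836 the control mean is 99.0% and the 1 mM mean 97.2%, and none of these sites passed the adjusted threshold.

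The doses did not differ at any site past the threshold either. Chromosome 19 position 30343379 was at 98.3% ± 1.38 at 0.1 mM and 92.7% ± 4.25 at 1 mM, with at least 120 reads per library (SD, n = 4; edgeR adjusted p = 0.594). Without 1 mM library 1, at 86.7% with the others at 92.6 to 95.8%, the difference there went from -5.64 to -3.65 points (edgeR adjusted p = 0.942). Differences were smaller at other methylated sites. Chromosome 18 position 44776729 was at 99.6% ± 0.218 and 98.3% ± 0.249, chromosome 7 position 73167573 at 95.1% ± 1.51 and 97.5% ± 0.479, and chromosome 10 position 137479 at 97.2% ± 0.721 and 98.6% ± 0.151. The unmethylated sites were chromosome 8 position 2751348, at 0.078% ± 0.042 and 0.372% ± 0.264, and chromosome 18 position 37192948, at 0.086% ± 0.038 and 0.392% ± 0.532. At the former, the difference of 0.294 points was 0.162 without 1 mM library 3. At the latter, the 1 mM mean rested on library 4 at 1.19%, with the other 1 mM pools at 0.091 to 0.181%, and the difference of 0.306 points was 0.04 without it. For these 6 sites the edgeR adjusted p was between 0.594 and 0.636. Both edgeR and limma called 0 of 2228 sites, with 109 and 114 at an unadjusted p under 0.05. The groups did not overlap at 55 sites (2.47%, with at most 2.86% by chance, less with tied levels). At least 10 points separated the means at 7 sites, 4 higher and 3 lower at 1 mM. Without 1 mM libraries 2 and 3, a setting chosen after seeing the data, edgeR called 2 sites, chromosome 8 position 56092585 and chromosome 18 position 37192948, where 1 of the 2 remaining 1 mM pools, library 4, was at 1.22% and 1.19% and the other at 0.128% and 0.091%.

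Changes at the 2 doses were compared across the 2228 sites on the log2 odds scale. Pearson's r across sites was 0.491 with the same 4 controls in both changes. Simulated groups without any change, set against shared controls, gave a mean of 0.499 and a range of 0.447 to 0.539 in 100 simulations. The covariance was 0.0848, below the simulated 0.133. As the simulation used 1 overdispersion value for all sites, this gap may reflect its setting. With the controls split so that each dose had its own pair, r averaged -0.006 over the 6 ways of splitting, with a range of -0.032 to 0.015. There were 0 shared calls, as neither dose had any.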

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

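All tests in this part were chosen after the results were seen. A library standing apart from the other 3 of its group was looked for in 57 groups of 4, in mean levels and at the named sites, and was found in 6. Chance gives about 1 in 20, or 2.85, for groups that were not selected. The named sites were selected for their small p, so that rate need not hold for them, and all flags but that in mean levels were at those sites. Mean methylation over all sites was 80.6% in control library 2. On chromosome 8 position 2751348, 1 mM library 3 was at 0.767%. Library 2 of the 0.1 mM group was at 1.81% on chromosome 11 position 21819918, and library 1 of that group at 99.3% on chromosome 18 position 44776729. On chromosome 18 position 37192948, 1 mM library 4 was at 1.19%.

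At chromosome 1 position 1292889, 1 mM library 4 was at 82.2%, apart from 92.7%, 94.7% and 93.7% in the other 1 mM pools. The site was called against control in some settings only. It was picked among 2228 sites for its small p and did not pass after adjustment, so chance stays open, as does exposure, which was not tested apart from that choice. Reads from a fragment other than the reference one may also contribute: the 2 ends of its reference fragment differed in depth by 8.05 on the log2 scale, more than in 86.3% of the other 1406 fragments, whose median difference was already 3.38, so this does not set the site apart. These explanations cannot be told apart with these values.

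The comparisons of unadjusted levels do not use the spiked standards. The standard with the lowest level was methylated at 2.57% in 1 mM library 1 and 1.78% in 1 mM library 3, above the 0.215 to 0.920% of controls. Incomplete SmaI digestion would also raise unmethylated genomic sites, but at the 212 sites under 1% library 1 was -0.043 points from the highest control, which argues against it there. In library 3, the highest of the 12 at these sites with 0.227%, they exceeded the highest control by 0.069 points and the standard exceeded it by 0.86, which argues against digestion as the whole source and leaves a small part open. Over the 234 sites under 10%, libraries 3 and 1 were the highest of the 12, at 0.646% and 0.613%, the direction that incomplete digestion predicts. The 0.1 mM libraries 2 and 1 were at 0.599% and 0.593%, also above the highest control, with the standard at 0.475% and 0.285%. At the 22 sites of 1 to 10% 1 mM library 1 was the highest, at 5.41%. At the sites under 1%, which digestion would also raise, it was at 0.115%, below the 0.126 to 0.158% of controls. That argues against digestion as the source of its 5.41%. For 1 mM library 3, a part of digestion in the difference of that class between 1 mM and control stays open. The standard is not embryo DNA, no biological explanation was tested, and the source of the signal stays open.

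Sites over 1000 bp from their neighbour took 11.6% and 13.1% of the reads in 1 mM libraries 2 and 3, against 7.48 to 10.7% in controls. Across the 12 libraries, a larger share went with a lower methylation level at these sites (Pearson's r = -0.944, permutation p = 5e-05; Spearman's rho = -0.909, permutation p = 0.00015). Leaving out the 2 libraries farthest from the median share, r was -0.746 (permutation p = 0.025), and within groups, from deviations, it was -0.920. No other relation between 2 measures across libraries is reported. This one is consistent with extra reads whose ends look unmethylated, such as those from broken DNA. Exposure to 1 mM stays open: an exact two-sided permutation test did not separate the 1 mM share from that of controls (p = 0.229), while 2 of the 4 libraries exceeded the highest control.

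Other splits of the 8 libraries of each comparison into 4 and 4 were fitted in the same way, 35 each with the real one. As many sites at an unadjusted p under 0.05 as the real 109 between 1 mM and control came from 21 of the 35 splits, with 141 as the highest of the others. For 0.1 mM against control, 16 of the 35 splits gave at least the real 113, and the highest other gave 173. Between the doses, 12 of the 35 splits gave at least 109, and the highest other gave 121. Chance cannot be excluded in any of the 3.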

How the results depend on the processing

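The counts of called sites stayed at 0 in all comparisons with minimums of 50 and 100 reads, sites at 5 to 95%, limma, the quasi-binomial model, centred libraries and adjusted levels. The setting with a change of at least 10 points only filters the calls of the main fit, so it could give nothing but 0. Between 0.1 mM and control, 2 sites were called with a minimum of 10 reads and 2 with the 2 groups alone. Leaving out each library gave 0 to 1 sites for 1 mM against control (1 without control library 1 and 1 without 1 mM library 4), 0 to 2 for 0.1 mM against control (1 without control library 1, 2 without control library 3, 1 without 0.1 mM library 4) and 0 to 0 between the doses. Chosen after seeing the data, limma with 50 reads and limma on the deposited table each called 2 sites for 1 mM against control; without 1 mM libraries 2 and 3 there were 3, and 2 between the doses. The cause was not tested. With the replicate number as a block, 4 sites were called for 1 mM (chromosome 1 position 1292889, chromosome 5 position 14890555, chromosome 6 position 4440116 and chromosome 8 position 56092585), 2 for 0.1 mM (those on chromosomes 1 and 6) and 0 between doses; same-numbered libraries deviated together no more than others (median correlation 0.002, range -0.062 to 0.041), so the numbers were not taken to pair pools, and the blocked mean differences (0.133, -0.018 and 0.15 points, exact sign-flip p between 0.5 and 1) could not have passed, 0.125 being the smallest p possible.

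No mean difference passed the threshold. Over all sites, 1 mM minus control without control library 2 came nearest, at 0.284 points (exact permutation p = 0.0571). Between 1 mM and control the median of sites at 10 to 90% gave -0.053 points, read-weighted levels 0.063, adjusted levels 0.247, leaving out 1 mM libraries 2 and 3 (chosen after seeing the data) 0.279, and leaving out single libraries 0.048 to 0.284. Between 0.1 mM and control, the same median gave -0.587, read-weighted levels 0.112, adjusted levels 0.007, and leaving out libraries -0.133 to 0.134. Between the doses, the median gave 0.534, read-weighted levels -0.049, adjusted levels 0.24, leaving out 1 mM libraries 2 and 3 0.296, and leaving out single libraries 0.065 to 0.266. The cause was not tested. No single class could have passed, so settings of the class tests say nothing of stability. The correlation of the 2 doses went from 0.491 to -0.006 with split controls. Of 357 values under other settings of the 15 named sites, 3 of which stand in 2 comparisons, 337 kept their side of the threshold, 20 passed it and 0 turned sign. The sign could turn only where libraries were left out or adjusted levels were used. The remaining settings keep the same difference in points, so the absence of turns there was fixed in advance. The gene lists, camera, fry and the promoter definitions were not run. At sites of 10 to 90% the median replicate SD was 2.87 points, beside a median binomial SD of 2.47 points, a comparison that understates the spread beyond counting error. At this depth and number of pools, and with the single simulated overdispersion, edgeR recovered 33.5% of such sites with odds changed by a factor of 2. That was in the simulated comparison of 1 mM with control, and how far depth sets that share was not tested.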

Other observations

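Tests in this part were all chosen after the values were seen. Unmethylated CCCGGG sites came in groups. Where 1 of 2 adjacent analysed sites was under 10% and they lay over 100 and up to 300 bp apart, both were under 10% in 62 of 66 pairs (93.9%), and at 300 to 600 bp in 35 of 39 (89.7%). Beyond 50000 bp this held for 10 of 218 pairs (4.59%). Pearson's r of the levels of adjacent sites, across pairs of sites that are not independent replicates, was 0.892 at 100 to 300 bp, 0.793 at 600 to 5000 bp and 0.0694 at 5000 to 50000 bp.

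The share of analysed sites under 10% was 21.3% on chromosome 8 (23 of 108, exact Clopper-Pearson 95% interval 14.0 to 30.2%) and 20.0% on chromosome 5 (20 of 100, 12.7 to 29.2%), and 3.85% on chromosome 12 (3 of 78, 0.800 to 10.8%). A hypothesis that chromosomes differ beyond the grouping of neighbouring sites was tested by shuffling 1494 clusters of sites over chromosomes. The chi-square of 67.2 was not beyond chance (median of shuffles 46.6, permutation p = 0.085 in 10000 shuffles), so uneven grouping of sites is not excluded as its source.

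The deepest reads came from chromosome 4 between positions 61293852 and 61299689, where 14 analysed sites took 1.91 to 5.35% of the reads of a library. The most read site, at position 61299279, had 231229 reads over the 12 libraries, against a median of 4401 for an analysed site, and was methylated at 57.3%. Of the 14 sites, 13 lay between 10 and 90%, in a genome where most analysed sites are either nearly full or empty. Such depth and partial methylation may reflect a repeated sequence whose copies differ; copy number was not measured. The read-weighted level was 62.1% ± 0.940 in controls, 61.8% ± 2.80 at 0.1 mM and 60.1% ± 2.44 at 1 mM (SD, n = 4). A hypothesis that 1 mM arsenite lowers it was tested with an exact two-sided permutation test, which the difference of -1.98 points did not pass (p = 0.2).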
